A study of Mus musculus with 6 samples.

How the data were processed

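Gene-level RNA counts of 6 libraries were analysed: 2 from unmodified E14TG2a mouse embryonic stem cells (WT), 2 from a METTL3 knockout line (KO) and 2 from a line with the METTL3 D395A substitution (D395A). Total RNA had been depleted of ribosomal RNA and turned into stranded libraries. The authors deposited 1 table of HTSeq counts per library, with 24984 gene symbols and the summary lines of HTSeq. Per the submitters' processing notes, reads had been trimmed with Trimmomatic 0.36, aligned to the mouse genome with STAR 2.7 and counted with HTSeq 0.11.2. The strand setting of the counting step and the annotation release are not given in the sources used here, so genes that overlap another gene on the opposite strand carry uncertain counts. Circular RNA and m6A itself were not analysed here.

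The summary lines of HTSeq (reads outside genes, ambiguous reads and reads aligned to several places) were left out of all tests. They held 36.1% and 36.1% of the lines' total in WT replicates 1 and 2, 37.6% and 29.0% in KO, and 44.2% and 40.4% in D395A. Reads outside genes alone held 30.2% and 30.2% in WT, 31.1% and 22.3% in KO, and 37.3% and 33.8% in D395A. The precursor of ribosomal RNA, Rn45s, took 10.8% and 11.2% of gene counts in WT, 16.7% and 15.7% in KO, and 14.3% and 13.9% in D395A. It was kept, since scaling by trimmed means (TMM) is little affected by 1 gene.

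Gene positions came from the GENCODE mouse annotation (release M21, GRCm38), in which 97.89% of the symbols were found, and 3853 symbols had exons that overlap an exon of another gene on the opposite strand. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on low counts (15663 genes kept), TMM factors, estimateDisp, and the quasi-likelihood fit and F test with all 6 libraries in 1 model, without covariates. This leaves 3 residual degrees of freedom. The biological coefficient of variation was 6.00% and the prior degrees of freedom were 9.26. P-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold, and counts are also given at an absolute log2 fold change of at least 1. The comparisons were KO against WT, D395A against WT, and D395A against KO as the test of the difference between the mutant lines. Levels are TMM-scaled CPM (counts scaled to a common library size) as mean ± SD over 2 libraries, and fold changes are log2 ± SE of the fit. All p-values measure only the spread between these libraries. Whether the 2 libraries of a group came from separate cultures or separate clones is not stated.

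A single count equalled 0.0247 CPM in the deepest library (WT replicate 1) and 0.0437 CPM in the shallowest (D395A replicate 1). Where a group held 0 counts, the fold is given as a lower bound against a floor of 3 counts over the group, which is 0.0390 CPM in WT, 0.0429 CPM in KO and 0.0504 CPM in D395A. Where a group held 1 to 3 counts, the ratio of the groups is given with its exact 95% interval. These intervals and floors cover counting error only. On data simulated from these counts with 200 changed genes, the test recovered 79.1% of 2-fold changes for KO against WT, 73.1% for D395A against WT and 79.1% for D395A against KO. Of the calls in those simulations, 12.6%, 12.0% and 8.67% were false. These shares rest on 1 draw per comparison with few changed genes. In the data 66.2%, 70.3% and 50.4% of genes were called, so the shares do not carry over to the reported calls.

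Before the data were examined, 30 gene lists were fixed (pluripotency states, germ layers, other cell types, RNA methylation, metabolism, stress and complexes), with members of the ribosomal, respiratory chain, proteasome, HOX and small RNA classes taken by name. Each list with at least 5 measured members was tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists. With a correlation estimated from the data, camera called 0 lists in each comparison (1, 0 and 1 lists at an unadjusted p under 0.05), with lowest adjusted p of 0.499 for KO against WT, 0.570 for D395A against WT and 0.373 for D395A against KO. The directional fry test called 23, 23 and 16 lists, but it asks only whether the genes of a list move on balance one way and compares them with no other genes. The list counts below therefore rest on the preset correlation. In 20 draws of simulated unchanged groups for KO against WT, the only comparison drawn, camera at the preset correlation called 1 list in 1 draw. Genes were drawn independently of each other there, so these draws cannot show whether the preset correlation is too low. Medians of the called lists stayed the same to 2 decimals when members at 0 counts were set to their bound.

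The named genes followed a rule fixed at the same time. Mettl3, Mettl14, Wtap, Nanog, Sox2, Klf4, Pou5f1, Esrrb and Myc are always named. For each comparison with WT, the 8 largest rises and 8 largest falls past the test are named, among genes changed at least 2-fold with a mean of at least 2 CPM in the higher group and no overlap between the libraries of the groups. The 5 largest each way are named for D395A against KO, and 6 each way among genes past the test in both comparisons with WT. Unnamed gene models and small RNA symbols were passed over in these ranks. For each list described, up to 4 members with the smallest p are named. Some genes that the rule selects are not reported here. Gene families, chromosome medians, Y-linked genes, Xist and the groups of genes that set single libraries apart were chosen after the data had been seen.

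The alternatives were DESeq2 1.42.0 size factors, total counts, no filter, a stricter filter (1 CPM in at least 4 libraries), the DESeq2 Wald test, limma-voom, the robust quasi-likelihood fit, the replicate number as a block, fits to the 4 libraries compared, scaling without short structured RNA and mitochondrially encoded genes, and leaving out each library in turn. Added after the data had been seen were tests without genes that overlap on the opposite strand and without chromosomes 8, 11 and Y. These drop genes from the finished fit and repeat only the adjustment of p, and for the chromosomes also camera. Further additions were fits without D395A replicate 1 and KO replicate 2 together, and with a crossed block.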

Results

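RNA abundance was measured in mouse E14TG2a embryonic stem cells grown in N2B27, a serum-free medium. The 6 libraries form 3 groups of 2: unmodified cells (WT), a METTL3 knockout line (KO) and a line carrying METTL3 D395A, a substitution in the catalytic motif of the enzyme. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA, and the design text gives the interplay of m6A with circular RNA as the aim. Gene counts totalled 40476809 and 36136543 in WT, 35851584 and 35613626 in KO, and 22859491 and 35784699 in D395A. Levels are CPM, counts scaled to a common library size (mean ± SD, n = 2 libraries per group), and fold changes are log2 values ± SE. The 2 libraries of each group differed by more than sampling noise, with a chi-square per degree of freedom of 3.26 in WT, 6.73 in KO and 11.7 in D395A.

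Mettl3, the targeted gene, fell from 30.0 ± 2.17 CPM in WT to 6.99 ± 1.17 CPM in KO, a log2 fold change of -2.10 ± 0.11 (adjusted p = 6.5e-09). It was also lower in D395A, at 22.2 ± 1.59 CPM (-0.43 ± 0.10, adjusted p = 0.0022), and D395A stood above KO by 1.67 ± 0.12 (adjusted p = 1.2e-07). Single libraries held 28.5 and 31.6 CPM in WT, 7.82 and 6.17 CPM in KO, and 21.1 and 23.4 CPM in D395A. Mettl3 is a protein-coding gene on the minus strand of chromosome 14 (GRCm38, 52294841 to 52305128), and 18.38% of its exon bases overlap exons of Tox4 on the opposite strand. Mettl14, the partner that binds METTL3, fell from 32.3 ± 0.38 CPM to 20.1 ± 1.02 CPM in KO (-0.69 ± 0.08) and to 25.2 ± 2.77 CPM in D395A (-0.35 ± 0.08). Its level in D395A exceeded that in KO by 0.34 ± 0.09 (adjusted p = 0.0064), but by 0.21 without D395A replicate 2 (adjusted p = 0.093). Wtap, which brings the writer complex to its sites in the nucleus, rose from 95.3 ± 0.0512 CPM to 254 ± 6.32 CPM in KO (1.41 ± 0.06, adjusted p = 1.2e-09) and to 191 ± 5.5 CPM in D395A (1.00 ± 0.06, adjusted p = 2e-08).

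Other writers, readers and erasers of m6A moved both ways. Of 27 genes of this machinery measured, 10 were higher and 11 lower in KO, and 13 were higher and 9 lower in D395A, also when adjusted over the list alone. The list passed the test in neither comparison (adjusted p = 0.981 and 0.610), and 4 of its members lie on chromosomes 8 or 11. In KO its median was -0.03, while its mean of 0.04 and the test pointed up. Ythdf2, a reader that promotes decay of methylated mRNA, rose by 1.30 ± 0.07 in KO and 1.25 ± 0.07 in D395A. Alkbh5, a demethylase, fell from 391 ± 9.71 CPM to 182 ± 9.56 CPM in KO (-1.10 ± 0.07). Rbm15b, an adaptor of the writer complex, rose by 0.97 ± 0.06 in D395A, and Mettl16, a separate methyltransferase, fell by 0.96 ± 0.07 there. Among 29 measured genes for proteins that act on circular RNA formation, export or decay, 5 were higher and 15 lower in KO, and 7 were higher and 15 lower in D395A. This list did not pass either (adjusted p = 0.184 and 0.149), and 6 of its members lie on chromosomes 8 or 11. Median log2 fold changes on chromosomes 8 and 11 were -0.48 and -0.43 in KO and -0.39 and -0.49 in D395A. The fall of a member of either list on these chromosomes is not set apart from that shift. Mbnl2, a splicing regulator, rose from 20.6 ± 0.465 CPM to 82.0 ± 2.48 CPM in KO (1.99 ± 0.07) and 44.7 ± 0.879 CPM in D395A (1.11 ± 0.07). Nova2, a neuronal splicing factor, fell by 1.75 ± 0.10 in KO and to 3.08 ± 0.706 CPM in D395A (-3.54 ± 0.13). Nudt21, a cleavage factor subunit, fell in both (-1.07 ± 0.06 and -0.66 ± 0.06), as did Upf1, a helicase of nonsense-mediated decay (-0.89 ± 0.06 in KO), and Ddx39, an export helicase (-1.11 ± 0.07 in D395A).

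**Figure D1:**
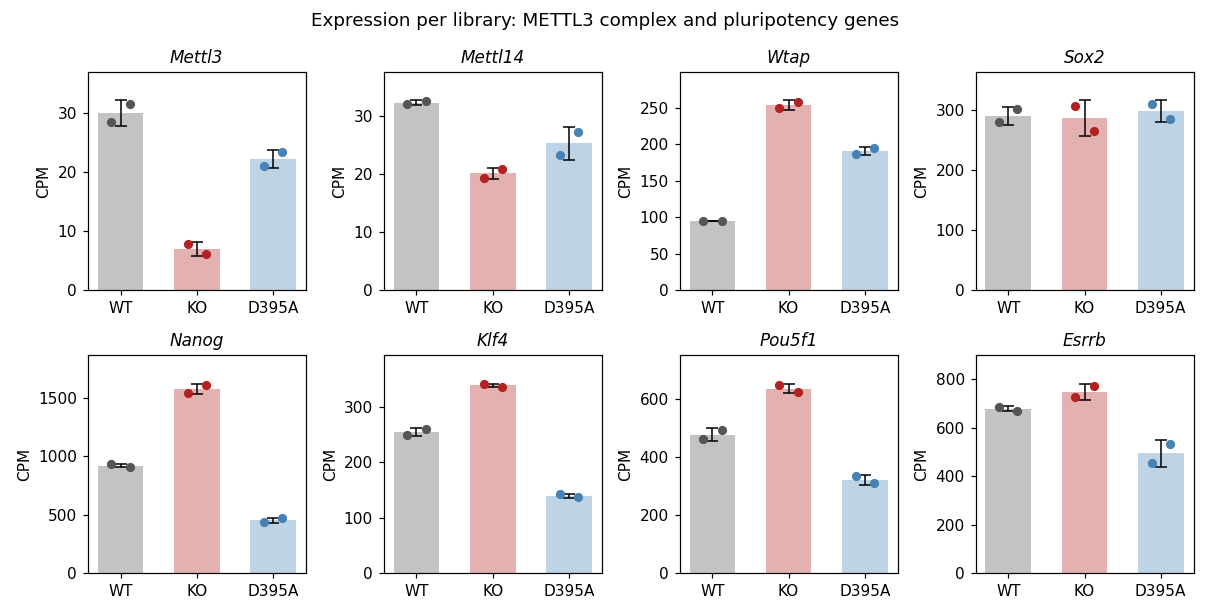
Levels of 8 genes in CPM (vertical axes start at 0) in WT, KO and D395A; bars are group means, error bars the SD over 2 libraries, and points single libraries. Mettl3 was lowest in KO at 6.99 CPM, while Nanog was highest in KO at 1577 CPM and lowest in D395A at 455 CPM.

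The comparison of KO with WT sets the METTL3 knockout line against unmodified cells. The labels name no separate clones of a genotype, so it cannot separate the loss of METTL3 from the history of the line. Several pluripotency factors were higher in KO. Nanog rose from 920 ± 14.9 CPM to 1577 ± 45.1 CPM (0.78 ± 0.07, adjusted p = 4e-07), Klf4 from 254 ± 7.64 CPM to 339 ± 3.18 CPM (0.41 ± 0.06, adjusted p = 7.1e-05) and Pou5f1 from 477 ± 22.1 CPM to 636 ± 17.0 CPM (0.42 ± 0.07, adjusted p = 0.00016). Sox2 stood at 291 ± 15.3 CPM and 286 ± 30.1 CPM (adjusted p = 0.82) and Esrrb at 678 ± 11.3 CPM and 749 ± 32.8 CPM (adjusted p = 0.13). Myc, a growth regulator, fell from 2.40 ± 0.045 CPM to 1.07 ± 0.233 CPM (-1.16 ± 0.29, adjusted p = 0.0037). Of 22 naive pluripotency genes, 8 rose and 10 fell, or 11 adjusted over the list alone. The list did not pass camera (adjusted p = 0.703). Klf2 rose to 888 ± 56.0 CPM (1.78 ± 0.07), whereas Dppa3, a maternal factor that protects DNA methylation, fell by 3.35 ± 0.13, Tcl1 fell by 2.02 ± 0.08 and Klf5 fell by 1.23 ± 0.08. Of 18 core pluripotency genes, 3 rose and 12 fell (adjusted p = 0.0943). Lin28a, which blocks maturation of let-7 microRNA, fell from 80.6 ± 7.79 CPM to 8.46 ± 1.35 CPM (-3.25 ± 0.12), Fbxo15 fell by 1.34 ± 0.06 and Utf1 by a log2 fold change of -0.81 ± 0.07, while Mycn rose by 0.94 ± 0.06.

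Glycolysis and hypoxia genes fell together in KO: 21 of 26 fell and 2 rose, with a median of -1.24 (adjusted p = 2.5e-06, and adjusted p = 0.641 with an estimated correlation). Slc2a1, the main glucose transporter, fell from 480 ± 21 CPM to 92.2 ± 2.47 CPM (-2.38 ± 0.07), Pfkp, a phosphofructokinase, from 320 ± 17.9 CPM to 49.3 ± 1.53 CPM (-2.70 ± 0.08), and Bnip3, a mitophagy receptor induced by low oxygen, from 92.7 ± 1.73 CPM to 11.5 ± 0.0348 CPM. Aldoc, an aldolase, fell by 2.29 ± 0.07. The integrated stress response fell as well, with 23 of 28 members lower and 3 higher (median -0.88, adjusted p = 3.4e-05, and adjusted p = 0.499 with an estimated correlation). Its central transcription factor Atf4 fell from 369 ± 12.5 CPM to 128 ± 2.11 CPM (-1.53 ± 0.07), Xbp1 of the unfolded protein response fell by 1.70 ± 0.06, and the mitochondrial folate enzymes Shmt2 and Mthfd2 changed by -1.57 ± 0.07 and -1.33 ± 0.06. Feedback genes of ERK signalling fell in 13 of 18 cases, and 5 did not pass (median -0.84, adjusted p = 0.00048, and adjusted p = 0.499 with an estimated correlation). Spry4, an inhibitor of receptor tyrosine kinase signalling, changed by -3.90 ± 0.20, Spry2 by -1.88 ± 0.08, Ier3 by -3.03 ± 0.20 and the ETS factor Etv4 by -1.72 ± 0.08. Of these 18 genes, 5 lie on chromosomes 8 or 11.

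Germline genes fell in KO, with 18 of 25 lower and 2 higher (median -1.38, adjusted p = 0.00011, and adjusted p = 0.641 with an estimated correlation). Dazl, a germ cell RNA-binding protein, fell from 142 ± 9.11 CPM to 16 ± 1.42 CPM (-3.15 ± 0.09), Hormad1, a meiotic chromosome axis protein, fell by 3.98 ± 0.13, Sohlh2 fell by 2.60 ± 0.09 and Tuba3a fell by 2.11 ± 0.08. Proteasome subunits fell in 28 of 36 cases and rose in 2 (median -0.52, adjusted p = 6.4e-05, and adjusted p = 0.763 with an estimated correlation), and 8 of the 36 lie on chromosomes 8 or 11. Psmc5, Psmb6, Psmd14 and Psmd11 changed by -1.05 ± 0.06, -1.05 ± 0.07, -0.85 ± 0.06 and -0.84 ± 0.06. These members were taken by p alone, so members on chromosomes 8 and 11 can lead. Falls of members there are not set apart from the shift of these chromosomes. Without genes of chromosomes 8, 11 and Y the proteasome list passed camera at the preset correlation (adjusted p = 9.9e-05). Targets of p53 rose, 22 of 27 with 3 lower (median 0.79, adjusted p = 0.00017, and adjusted p = 0.499 with an estimated correlation). Phlda3, an inhibitor of AKT, rose from 16.6 ± 1.86 CPM to 73.9 ± 2.84 CPM (2.15 ± 0.09), Perp by 1.94 ± 0.09, the antiproliferative gene Btg2 by 1.45 ± 0.07 and Ptp4a3 by 1.33 ± 0.07. Extraembryonic endoderm genes rose in 13 of 20 cases and fell in 3 (median 0.84, adjusted p = 0.032, and adjusted p = 0.499 with an estimated correlation). This call ended without KO replicate 2 (adjusted p = 0.0561) and without genes on chromosomes 8, 11 and Y (adjusted p = 0.278). Of the 20 members, 3 lie on chromosomes 8 or 11 and were dropped in the latter setting. Medians of these chromosomes were lower in KO, so the loss of the call does not tie the rise to that shift. The collagen IV genes Col4a1 and Col4a2 rose by 1.77 ± 0.09 and 2.65 ± 0.10, the laminin gene Lamb1 by 0.97 ± 0.06 and the endocytic adaptor Dab2 by 2.94 ± 0.13. Adjusted over the list alone, the members called lower were 22 for glycolysis, 19 for germline and 29 for the proteasome, and those called higher were 14 for extraembryonic endoderm. The other counts of these lists stayed as given.

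Imprinted RNAs held some of the largest single changes in KO. Hymai, an imprinted RNA of the Plagl1 locus, fell from 9.20 ± 0.669 CPM to 0 counts, at least 214-fold lower, and Plagl1 itself, a zinc finger factor, fell from 159 ± 0.186 CPM to 3.61 ± 1.21 CPM (-5.46 ± 0.16). Meg3, a long noncoding RNA of the Dlk1-Dio3 region, fell from 57.5 ± 2.29 CPM to 0.0574 ± 0.041 CPM (-9.88 ± 0.18, adjusted p = 5.9e-12), or -10.81 without KO replicate 2. Mirg, from the same region, was 392-fold lower (95% interval 108 to 3244, from 2 counts in KO), with fitted log2 values of -8.44 with all libraries, -11.59 without KO replicate 1 and -7.53 without KO replicate 2. Phlda2, an imprinted growth restrictor, rose by 3.45 ± 0.09. Over all 37 imprinted genes measured, 12 rose and 17 fell, and the list did not pass (adjusted p = 0.564).

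Among other large falls in KO, Usp26, an X-linked deubiquitinase, went from 59.2 ± 0.311 CPM to 0.516 ± 0.207 CPM (-6.83 ± 0.16), the phospholipase gene Pla2g1b changed by -6.61 ± 0.16 and the mitochondrial gene Ndufa4l2 by -6.19 ± 0.32. The X-linked Xlr5a fell from 12.4 ± 0.692 CPM to 0.115 ± 0.0415 CPM, Xlr5b was 166-fold lower (56.3 to 805) and Xlr4c was 173-fold lower (30.8 to 6885), with fitted log2 values of -9.41 without KO replicate 1 and -6.27 without KO replicate 2. Xlr genes are near-identical copies, so their single values are uncertain. The largest rises included the membrane protein gene Tmem151a, from 0.270 ± 0.0701 CPM to 14.4 ± 0.514 CPM (5.71 ± 0.20) and the synaptotagmin Syt13 from 0.364 ± 0.0074 CPM to 15.0 ± 1.08 CPM (5.35 ± 0.19). Sqor, a mitochondrial sulfide oxidase, had 0 counts in WT and 2.10 ± 0.284 CPM in KO, at least 54.0-fold higher. Other named rises, Scpep1os, B3gat2, Acat3 and Far2, each overlap a gene on the opposite strand (Scpep1, Smap1, Tcp1 and Ergic2). They rested on KO replicate 1, with 6.20 against 0.202 CPM in replicate 2 for Scpep1os, 3.81 against 0.230 CPM for B3gat2, 14.5 against 0.663 CPM for Acat3 and 8.02 against 0.230 CPM for Far2. Scpep1os was 248-fold higher than in WT (44.0 to 9832) and B3gat2 156-fold (27.6 to 6221). Their log2 fold changes were 7.59 and 6.93 with all libraries, but 3.63 and 3.82 without KO replicate 1. They were 9.735 and 9.073 without WT replicate 1, and 6.828 and 6.166 without WT replicate 2. Acat3 changed by 6.79 ± 1.47, or 3.28 without KO replicate 1, 10.98 without WT replicate 1 and 5.91 without WT replicate 2. Far2 changed by 5.27 ± 1.27, or 1.13 without KO replicate 1. The robust fit ended the calls of Scpep1os (adjusted p = 0.12), B3gat2 (0.104), Acat3 (0.124) and Far2 (0.15), and limma-voom those of Scpep1os (0.0622), Acat3 (0.145) and Far2 (0.142).

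In the edgeR quasi-likelihood test of KO against WT, 10368 of 15663 genes changed, 5263 higher and 5105 lower. Of these, 3809 changed at least 2-fold, 2142 higher and 1667 lower, and 2535 did so under the stricter filter on low counts.

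The comparison of D395A with WT sets the line with the altered catalytic motif against unmodified cells, and here too genotype and history of the line cannot be separated. Naive pluripotency genes fell: 18 of 22 were lower and 4 higher (median -0.95, adjusted p = 0.00052, and adjusted p = 0.570 with an estimated correlation). Tbx3, a naive state factor, fell from 282 ± 1.06 CPM to 18.4 ± 1.07 CPM (-3.93 ± 0.08), Tcl1, a coactivator of AKT, from 60.1 ± 2.45 CPM to 3.39 ± 0.151 CPM (-4.14 ± 0.10), Fgf4, the growth factor that starts ERK signalling in these cells, from 226 ± 0.877 CPM to 49.1 ± 3.98 CPM (-2.20 ± 0.07), and the junction gene Jam2 fell by 2.94 ± 0.07. Nanog fell to 455 ± 21 CPM (-1.01 ± 0.07, adjusted p = 3.3e-08), Klf4 to 140 ± 3.95 CPM (-0.86 ± 0.06), Pou5f1 to 323 ± 17.1 CPM (-0.57 ± 0.07) and Esrrb to 495 ± 55.5 CPM (-0.46 ± 0.08, adjusted p = 0.00023). Sox2 stood at 298 ± 17.9 CPM (adjusted p = 0.70) and Myc at 2.88 ± 0.0906 CPM (adjusted p = 0.42). Among 18 core pluripotency genes 12 fell and 4 rose (adjusted p = 0.0763).

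Genes of the 2-cell-like state rose in D395A, 11 of 14 with 1 lower (median 1.80, adjusted p = 0.0068, and adjusted p = 0.570 with an estimated correlation). Zscan4d rose from 0.769 ± 0.393 CPM to 15.0 ± 1.78 CPM (4.30 ± 0.25, or 4.91 without WT replicate 2), Zscan4c by 3.46 ± 0.21 and Zscan4a by 3.64 ± 0.29. These are near-identical copies, so their single values are uncertain. The list also holds Usp17 genes, and all 5 Zscan4 and all 4 Usp17 genes measured were called higher. Members of 1 family are not independent, so the count and p of the list may overstate its evidence. The autophagy receptor Calcoco2 fell by 3.22 ± 0.11. Imprinted genes rose in 21 of 37 cases and fell in 7 (median 0.46, adjusted p = 0.030, and adjusted p = 0.570 with an estimated correlation). H19, a maternally expressed noncoding RNA, rose from 0.891 ± 0.182 CPM to 34.0 ± 1.68 CPM (5.26 ± 0.14), the neighbours Peg10 and Sgce rose by 3.33 ± 0.10 and 3.38 ± 0.09, and the amino acid transporter gene Slc38a4 fell by 2.99 ± 0.07. Neuroectoderm genes did not pass as a list (adjusted p = 0.0675), with 11 of 15 higher and 3 lower. Sox21 rose from 3.23 ± 0.364 CPM to 35.4 ± 2.87 CPM (3.44 ± 0.12) and Sox11 by 3.46 ± 0.12, while the neuronal tubulin Tubb3 fell by 1.34 ± 0.07. Formative and primed state genes, 11 of 17 higher and 4 lower, did not pass either (adjusted p = 0.0649). N-cadherin (Cdh2) rose by 3.36 ± 0.11, Sox4 by 2.30 ± 0.07 and Sox3 by 2.80 ± 0.16, and the epithelial factor Grhl2 fell by 2.87 ± 0.17. Of 18 targets of Wnt signalling, 10 rose and 4 fell (adjusted p = 0.149), among them Sp5, which rose from 14.3 ± 2.04 CPM to 481 ± 41.3 CPM (5.06 ± 0.11).

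Glycolysis, proteasome and germline genes fell in D395A. Glycolysis and hypoxia genes were lower in 23 of 26 cases and higher in 2 (median -0.95, adjusted p = 3.8e-05, and adjusted p = 0.570 with an estimated correlation), with Ldha, lactate dehydrogenase, falling from 516 ± 17.5 CPM to 181 ± 3.56 CPM (-1.51 ± 0.06), Ndrg1 by a log2 fold change of -2.91 ± 0.11, Pfkp of -2.15 ± 0.07 and Bnip3 of -1.75 ± 0.06. Proteasome subunits were lower in 28 of 36 cases and higher in 2 (median -0.56, adjusted p = 5.1e-05, and adjusted p = 0.570 with an estimated correlation), with 8 members on chromosomes 8 or 11. Psmb6, Psmb3, Psmc5 and Psmd3 changed by -1.18 ± 0.07, -1.13 ± 0.07, -1.09 ± 0.06 and -1.06 ± 0.06. They were also taken by p alone, so members on chromosomes 8 and 11 can lead here too, and 6 of the 36 lie on chromosome 11. Falls of members there are not set apart from the shift of these chromosomes. Without genes of chromosomes 8, 11 and Y the list passed camera at the preset correlation (adjusted p = 0.00025). Germline genes were lower in 18 of 25 cases and higher in 4 (median -1.46, adjusted p = 0.00052, and adjusted p = 0.570 with an estimated correlation). Tuba3a, a tubulin of the testis, fell from 163 ± 3.23 CPM to 10.3 ± 1.37 CPM, and Hormad1 changed by -4.26 ± 0.13, Dazl by -3.65 ± 0.10 and Sohlh2 by -2.79 ± 0.09. Targets of p53 rose in 20 of 27 cases and fell in 2 (median 0.63, adjusted p = 0.0037, and adjusted p = 0.570 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 160 ± 4.34 CPM to 405 ± 3.52 CPM (1.34 ± 0.06), Ddit4l by 2.44 ± 0.11, Perp by 1.94 ± 0.09 and Phlda3 by 1.72 ± 0.09.

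Genes of cholesterol synthesis rose in D395A, 16 of 24 with 3 lower (median 0.41, adjusted p = 0.0097, and adjusted p = 0.570 with an estimated correlation). The synthesis enzymes Sc5d, Tm7sf2 and Nsdhl rose by 0.88 ± 0.07, 0.88 ± 0.09 and 0.76 ± 0.07. Replication-dependent histone genes rose in 25 of 34 cases and fell in 3 (median 0.52, adjusted p = 0.013, and adjusted p = 0.812 with an estimated correlation). Hist1h3i, Hist1h1d, Hist1h2bf and Hist1h1e rose by 1.05 ± 0.12, 0.92 ± 0.11, 0.87 ± 0.08 and 0.86 ± 0.09, with near-identical copies in the family. Ribosomal protein genes rose in 43 of 75 cases and fell in 4 (median 0.24, adjusted p = 0.0068, and adjusted p = 0.825 with an estimated correlation), but the list did not pass without D395A replicate 1 (adjusted p = 0.0889), and 8 members lie on chromosomes 8 or 11. Rps21 rose by 0.99 ± 0.09, Rpl41 by 0.79 ± 0.10, Rps19 by 0.60 ± 0.08 and Rpsa by 0.54 ± 0.07. The directional fry test called neither the histone nor the ribosomal list (adjusted p = 0.124 and 0.125). Adjusted over the list alone, 19 germline genes were lower and 12 genes of the 2-cell-like state higher, and the other counts of the lists called in D395A stayed as given.

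Several developmental genes with 0 counts in WT appeared in D395A. Pcdh18, a protocadherin, reached 6.64 ± 1.27 CPM, at least 165-fold higher, the forkhead gene Foxb1 5.38 ± 0.0783 CPM (at least 138-fold), Hoxa2 4.23 ± 0.884 CPM (at least 105-fold), Wnt8a 4.09 ± 0.368 CPM (at least 106-fold) and the noncoding RNA Hotairm2 3.70 ± 0.846 CPM (at least 91.8-fold). Cd247, Samd11 and Pmch were at least 231-fold, 115-fold and 102-fold higher. These last genes and Foxb1 overlap a gene on the opposite strand (Pou2f1, Noc2l, Parpbp and B230323A14Rik), and the robust fit ended the calls of Cd247 (adjusted p = 0.0699), Samd11 (0.074) and Pmch (0.11). Xlr5a and Xlr5b had 0 counts in D395A, at least 246-fold and 141-fold lower, and Xlr4b and Xlr4a were 327-fold (58.3 to 12926) and 271-fold (74.7 to 2240) lower. Pramel6 was at least 136-fold lower, Samd7 at least 107-fold, the olfactory receptor gene Olfr153 at least 56.7-fold, and AV320801 221-fold (39.3 to 8740). Without D395A replicate 1 and without replicate 2, the fitted log2 values were -10.64 and -6.89 for Xlr4b, -7.28 and -11.29 for Xlr4a and -10.08 and -6.32 for AV320801.

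The edgeR test of D395A against WT called 11011 of 15663 genes, 5687 higher and 5324 lower. At least 2-fold changes were seen in 4545, of which 2660 were higher and 1885 lower, and in 2848 under the stricter filter.

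**Figure D2:**
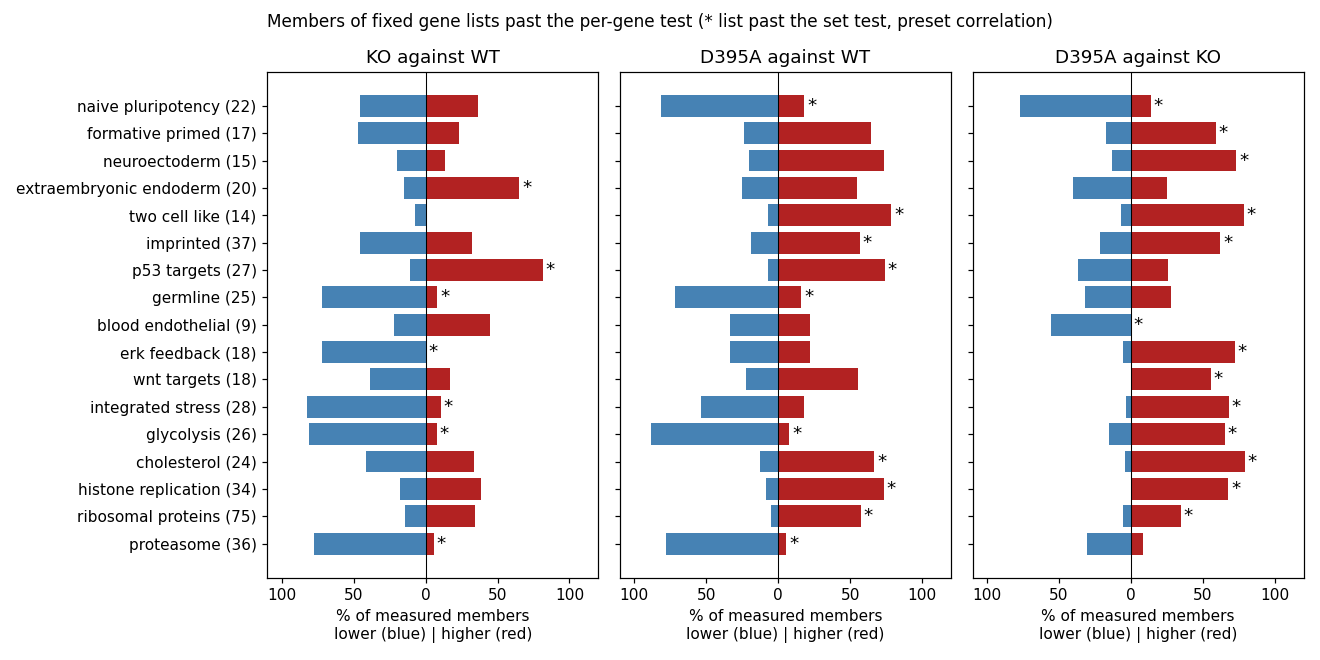
Share of measured members past the test and lower or higher (percent, horizontal axis) for 17 gene lists in each of the 3 comparisons; a star marks lists past the camera test at the preset correlation. Naive pluripotency genes were lower in D395A (18 of 22), while in KO 8 rose and 10 fell.

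The direct comparison of D395A with KO tests where the mutant lines differ. Naive pluripotency genes were lower in D395A than in KO, 17 of 22 with 3 higher (median -0.89, adjusted p = 9.8e-05, and adjusted p = 0.373 with an estimated correlation). Nanog differed by -1.79 ± 0.07 (adjusted p = 6.1e-10), Klf4 by -1.28 ± 0.06, Pou5f1 by -0.98 ± 0.07 and Esrrb by -0.60 ± 0.08. Tbx3, Jam2 and Fgf4 differed by -4.42 ± 0.08, -3.03 ± 0.07 and -2.83 ± 0.07, whereas Dppa3 was higher in D395A by 4.87 ± 0.12. Myc was higher by 1.42 ± 0.29 (adjusted p = 0.0015) and Sox2 did not pass (0.06 ± 0.08, adjusted p = 0.57). The core pluripotency list did not pass (adjusted p = 0.634), with Lin28a 4.03 ± 0.12 higher and Tdgf1, a Nodal coreceptor, lower (-3.15 ± 0.08). Genes of the 2-cell-like state were higher in 11 of 14 cases and lower in 1 (median 2.62, adjusted p = 0.00051, and adjusted p = 0.373 with an estimated correlation). Zscan4d and Zscan4c differed by 3.92 ± 0.24 and 3.76 ± 0.22, and Calcoco2 by -3.28 ± 0.11. Genes of the Zscan4 and Usp17 families again count as separate members here, though they are not independent.

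Neuroectoderm genes were higher in D395A than in KO in 11 of 15 cases and lower in 2 (median 1.16, adjusted p = 0.0039, and adjusted p = 0.373 with an estimated correlation), among them Sox21 (3.29 ± 0.12) and Sox11 (2.58 ± 0.11), while the adhesion gene Ncam1 was lower (-2.85 ± 0.07). Formative and primed genes were higher in 10 of 17 cases and lower in 3 (median 0.67, adjusted p = 0.0051, and adjusted p = 0.373 with an estimated correlation), with Cdh2 at 3.06 ± 0.11, Sox3 at 3.61 ± 0.17 and Sox4 at 1.37 ± 0.06. Targets of Wnt signalling were higher in 10 of 18 cases, and 8 did not pass (median 0.73, adjusted p = 0.0039, and adjusted p = 0.373 with an estimated correlation), and 6 members lie on chromosomes 8 or 11. The Wnt-induced factor Lef1 differed by 4.82 ± 0.18, the Wnt inhibitor Notum by 3.99 ± 0.09, Sp5 by 3.11 ± 0.10 and the receptor Fzd7 by 1.26 ± 0.07. Imprinted genes were higher in 23 of 37 cases and lower in 8 (median 0.82, adjusted p = 0.0039, and adjusted p = 0.373 with an estimated correlation). H19 differed by 5.62 ± 0.15, the zinc finger gene Peg3 by 3.67 ± 0.08 and Phlda2 by -2.74 ± 0.09, and Meg3 by 9.52 ± 0.18, or 10.44 without KO replicate 2. Markers of blood and endothelium were lower in 5 of 9 cases, and 4 did not pass (median -1.23, adjusted p = 0.0067, and adjusted p = 0.373 with an estimated correlation), a call that ended without chromosomes 8, 11 and Y (adjusted p = 0.111). The members named by the rule were Pecam1 (-1.23 ± 0.08), which stem cells also express, Cd68 (-1.59 ± 0.13), Cd34 (-1.91 ± 0.37) and Tal1 (-1.39 ± 0.34).

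ERK feedback genes were higher in D395A than in KO in 13 of 18 cases and lower in 1 (median 0.91, adjusted p = 0.00071, and adjusted p = 0.373 with an estimated correlation), with 5 members on chromosomes 8 or 11. Spry4 differed by 2.86 ± 0.21, Spry2 by 1.27 ± 0.09, Spred1 by 1.05 ± 0.06 and Etv4 by -2.45 ± 0.11. Integrated stress genes were higher in 19 of 28 cases and lower in 1 (median 0.46, adjusted p = 0.00029, and adjusted p = 0.373 with an estimated correlation). Atf4 stood at 407 ± 17.0 CPM in D395A against 128 ± 2.11 CPM in KO (1.67 ± 0.07), and Vldlr, Chac1 and Xbp1 differed by 1.76 ± 0.11, 1.25 ± 0.08 and 0.92 ± 0.06. Cholesterol genes were higher in 19 of 24 cases and lower in 1 (median 0.33, adjusted p = 0.00012, and adjusted p = 0.491 with an estimated correlation), with Mvd, Hmgcs1, Lss and Idi1 at 1.09 ± 0.06, 1.05 ± 0.06, 0.97 ± 0.06 and 0.82 ± 0.07. Histone genes were higher in 23 of 34 cases, and 11 did not pass (median 0.35, adjusted p = 0.0023, and adjusted p = 0.918 with an estimated correlation), among them Hist3h2ba (1.27 ± 0.17), Hist1h1e (1.07 ± 0.09), Hist2h3b (0.71 ± 0.08) and Hist1h2bf (0.66 ± 0.08), but fry did not call them (adjusted p = 0.142). Glycolysis genes were higher in 17 of 26 cases and lower in 4 (median 0.28, adjusted p = 0.030, and adjusted p = 0.918 with an estimated correlation), with Slc2a1 at 2.13 ± 0.07, Bnip3 at 1.25 ± 0.07, Aldoc at 1.05 ± 0.08 and Pdk1 at 0.91 ± 0.06. This call ended without D395A replicate 2 (adjusted p = 0.0616), without KO replicate 1 (adjusted p = 0.0879) and without chromosomes 8, 11 and Y (adjusted p = 0.111). Ribosomal protein genes were higher in 26 of 75 cases and lower in 4 (median 0.14, adjusted p = 0.032, and adjusted p = 0.918 with an estimated correlation), with Rps20 at 0.54 ± 0.09, Rpl10 at 0.45 ± 0.07, Rpl23 at -0.85 ± 0.09 and Rpl19 at -1.06 ± 0.09. The ribosomal call ended in fry (adjusted p = 0.377), without a filter (0.0703), and without WT replicate 1 (0.0778), WT replicate 2 (0.0604), D395A replicate 1 (0.795), KO replicate 1 (0.0983) or KO replicate 2 (0.195). Adjusted over the list alone, 6 blood and endothelial and 6 glycolysis genes were lower, 11 Wnt targets and 24 histone genes were higher, and the other counts stayed as given.

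Foxb1 was at least 126-fold higher in D395A than in KO, the carbonic anhydrase gene Car4 422-fold (75.3 to 16731) and Hotairm2 125-fold (34.2 to 1039), with fitted log2 values of 10.67 and 9.98 without KO replicate 1 and 7.54 and 5.92 without KO replicate 2. Ptn, the growth factor pleiotrophin, stood at 12.1 ± 1.87 CPM against 0.0569 ± 0.0804 CPM (7.63 ± 0.51), with 11.68 without KO replicate 1 and 6.67 without KO replicate 2. Sqor was 125-fold lower in D395A (22.1 to 4981; fitted log2 -9.27 without D395A replicate 1 and -5.51 without D395A replicate 2), the short-chain fatty acid receptor Ffar3 50.3-fold (16.9 to 246) and the inner ear gene Otog 40.6-fold (13.6 to 199). The Y-linked Zfy1 differed by -6.68 ± 0.23 (adjusted p = 3.1e-10). The edgeR test called 7889 of 15663 genes, 4154 higher and 3735 lower in D395A, and 2497 at least 2-fold (1313 higher and 1184 lower), or 1626 under the stricter filter.

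Both mutant lines shared many changes from WT. Past the test in both comparisons were 3853 genes higher in both and 3789 lower in both, where independent lists would share 1911 and 1735. A further 453 genes were higher in KO and lower in D395A, and 299 the reverse, where independent lists would give 1789 and 1854. Changes of at least 2-fold in both were shared by 1472 rises and 1036 falls. Across genes, the fold changes correlated with Pearson r = 0.775 and Spearman rho = 0.717, and genes are not independent replicates. The WT libraries are common to both comparisons, and in 20 simulated draws of unchanged groups with shared controls the medians were 0.486 and 0.429. The covariance, however, was 1.98 against a simulated median of 0.0551, and at most 3 calls were shared in a draw. The WT libraries cannot be divided between the comparisons with only 2 of them, so a trait of WT alone would appear in both.

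Shared rises named by the rule included Tshz1, a zinc finger factor, at 0.506 ± 0.298 CPM in WT, 17.0 ± 0.481 CPM in KO (5.09 ± 0.20) and 21.3 ± 1.39 CPM in D395A (5.42 ± 0.20), with 5.83 and 6.15 without WT replicate 2. Fbxl7, an F-box gene, rose by 5.13 ± 0.31 in KO and 6.95 ± 0.28 in D395A. Its values were 4.36 and 6.16 without WT replicate 1, and 6.61 and 8.42 without WT replicate 2. The others were Scpep1os, B3gat2, Acat3 and Far2. Of these, Scpep1os and B3gat2 were 693-fold (124 to 27414) and 672-fold (120 to 26597) above WT in D395A. Their fitted log2 values were 11.23 and 11.18 without WT replicate 1, and 8.33 and 8.27 without WT replicate 2. The robust fit ended the D395A calls of Scpep1os (adjusted p = 0.059) and Far2 (0.072). Acat3 rose by 8.60 ± 1.27 in D395A, or 12.78 without WT replicate 1 and 7.71 without WT replicate 2, and Far2 by 6.70 ± 1.17. Shared falls included Smc1b, a meiotic cohesin subunit, at 49.7 ± 5.21 CPM in WT, 1.00 ± 0.112 CPM in KO (-5.63 ± 0.14) and 0.815 ± 0.172 CPM in D395A (-5.97 ± 0.15). Usp26 changed by -7.45 ± 0.18 in D395A, or -8.41 without D395A replicate 2. Pramel6 fell in KO by a log2 fold change of -5.41 ± 0.48, or -7.72 without KO replicate 1 and -4.57 without KO replicate 2, and Xlr5a, Xlr5b and Xlr4c complete the shared falls.

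**Figure D3:**
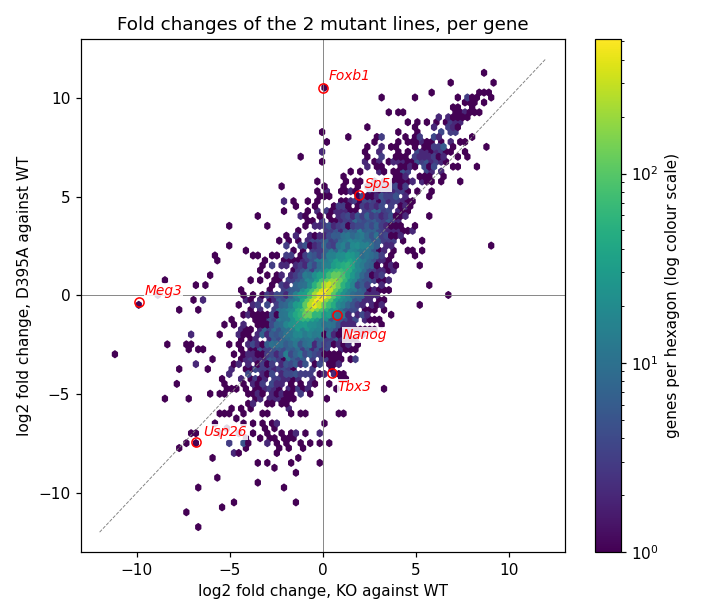
Log2 fold change of D395A against WT (vertical axis) over that of KO against WT (horizontal axis) for the genes tested, as a density of genes per hexagon, with named genes in red. The Pearson correlation across genes was 0.775, against 0.486 in simulated unchanged groups with shared WT libraries; fitted values of genes at 0 counts in a group depend on the prior count.

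Some differences between the groups followed chromosomes. Over 9425 genes with a mean log2 CPM above 3, the median log2 fold change on chromosome 8 was -0.48 in KO and -0.39 in D395A (528 genes), and on chromosome 11 it was -0.43 and -0.49 (808 genes). The other autosomes had medians between -0.11 and 0.14 in KO and between -0.04 and 0.20 in D395A. On chromosome 8, 68.0% of genes were past the test and lower in KO and 64.6% in D395A, and on chromosome 11 the shares were 65.8% and 69.3%. A segment of chromosome 11 with 80 of these genes (88830792 to 98587368) had a median of -0.03 in KO and -0.62 in D395A, and Rpl19, Rpl23, Psmb3 and Calcoco2 lie in it. Of 6 Y-linked genes, in D395A Zfy1 changed by -5.90 ± 0.25, Eif2s3y by -2.51 ± 0.08, Ddx3y by -1.77 ± 0.08, Uty by -1.71 ± 0.11 and Kdm5d by -0.54 ± 0.14, while Usp9y rose by 1.41 ± 0.23. In KO Kdm5d rose by 3.02 ± 0.11, Usp9y by 5.13 ± 0.17, Zfy1 by 0.77 ± 0.12 and Ddx3y by 0.20 ± 0.07, Eif2s3y fell by 0.57 ± 0.07 and Uty did not pass (0.03 ± 0.09).

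**Figure D4:**
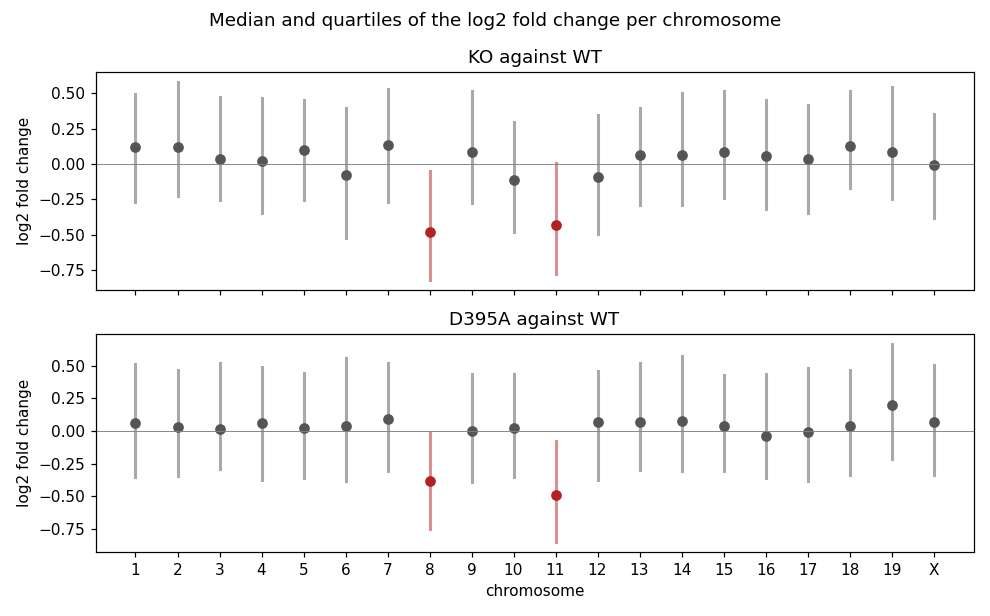
Median (points) and quartiles (lines) of the log2 fold change (vertical axis) per chromosome (horizontal axis) for KO and D395A against WT, with chromosomes 8 and 11 in red. Both stand below the other autosomes, at -0.48 and -0.43 in KO.

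Libraries also differed within groups in ways that touch the genes above. Xist, the noncoding RNA of X inactivation, had 1 and 0 counts in WT, 125 and 1 in KO replicates 1 and 2, and 145 and 176 in D395A, while Tsix, its antisense partner, had 912 and 763, 669 and 546, and 383 and 652. Over 52 genes within a far more abundant gene on the opposite strand, the median level relative to that gene was 0.581% and 1.09% in WT, 2.59% in KO replicate 1, 0.511% in KO replicate 2, and 4.73% and 3.43% in D395A. A group of 169 genes, among them the developmental regulators Nr2f2, Nr2f1 and Bcl11a, was higher in D395A replicate 1 and KO replicate 2 than in the other library of each line. Bcl11a stood at 6.26 and 0.665 CPM in D395A replicates 1 and 2 and at 0.142 and 3.08 CPM in KO replicates 1 and 2. Of these 169 genes, 48 were called higher in KO and 106 in D395A against WT.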

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

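Chosen only after the results were seen were the test of METTL3 genotype for chromosomes 8 and 11, the test of antisense transcription, the tests of neural RNA and of opposite-strand reads for the developmental genes, and the make-up of the gene groups of the last 2 patterns; the remaining tests were written before their results.

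The mutant lines differed from each other in the direct test of D395A against KO. The median log2 difference was -0.89 for naive pluripotency genes and -1.23 for markers of blood and endothelium. It was 2.62 for genes of the 2-cell-like state, 1.16 for neuroectoderm, 0.82 for imprinted genes, 0.67 for formative and primed genes and 0.73 for Wnt targets. ERK feedback genes stood at 0.91, integrated stress at 0.46, replication-dependent histones at 0.35, cholesterol synthesis at 0.33, glycolysis at 0.28 and ribosomal proteins at 0.14. The glycolysis call ended in 3 other settings and the ribosomal call in 7, the histone call ended in fry and the blood and endothelium call without chromosomes 8, 11 and Y. With an estimated correlation camera called 0 of these lists, with a lowest adjusted p of 0.373. Genes past the test in both lines with opposite signs against WT differed as well: Nanog by -1.79, Klf4 by -1.28, Pou5f1 by -0.98 and the Y-linked Zfy1 by -6.68. Ffar3 and Otog, both with 3 counts in D395A, differed by fitted values of -5.53 and -5.25, which depend on the prior count, and as ratios by 50.3-fold (16.9 to 246) and 40.6-fold (13.6 to 199). Their rise in KO against WT was less firm, at 1.31 for Ffar3 (adjusted p = 0.012) and 0.99 for Otog (adjusted p = 0.043). It did not pass without WT replicate 1 (Ffar3 1.20, Otog 0.93), WT replicate 2 (1.43 and 1.05) or KO replicate 1 (0.99 and 0.75), and for Otog also not with total counts, the DESeq2 test or the replicate block. Reads outside annotated genes, which no comparison uses, made up 37.3% and 33.8% of the total in D395A, 31.1% in KO replicate 1 and 22.3% in KO replicate 2, against 30.2% in each WT library.

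Genes of chromosomes 8 and 11 were lower in both mutant lines, with medians of -0.48 and -0.43 in KO and -0.39 and -0.49 in D395A. A bias of GC content, transcript length or expression level is argued against, since after a fit on all of them the residual nearest to 0 was still -0.385. A difference in copy number between the WT culture and the mutant lines is a candidate explanation. Relative to the other autosomes, the medians of chromosomes 8 and 11 were -0.537 and -0.485 in KO and -0.429 and -0.535 in D395A. These are somewhat short of the -0.58 that 2 copies against 3 would give in every cell. The shift ran along most of both chromosomes, as 19 of 20 windows of similar gene number lay below every other autosome in both comparisons. The exception, 80 genes of chromosome 11, had a median of -0.03 in KO and -0.62 in D395A, so there the lines differed from each other, which stays open. Whether the METTL3 genotype itself acts on these chromosomes cannot be told apart from the history of the lines, because the labels name no separate clones of a genotype. The mutant lines differed from each other by a median of at most 0.0679 over the genes of chromosome 8 or of chromosome 11.

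A group of 240 genes was high in both D395A libraries and KO replicate 1 and low in KO replicate 2 and WT. All of these differences were reversed in 9 genes, which were low in D395A and KO replicate 1. Higher antisense transcription with the METTL3 genotype is argued against, as the KO libraries share that genotype, yet over 52 gene pairs the level relative to the partner was higher in replicate 1 by a median log2 ratio of 1.53 (quartiles 0.47 to 3.42). Reads counted for a gene on the opposite strand, in libraries of lower strand specificity, are a candidate explanation. Of 225 annotated genes in the group, 54.7% had at least 50% of exon bases within the bounds of a gene on the opposite strand, against 4.74% of other tested genes. The remaining genes of the group stay open, and of the rises named in the report with this profile, Scpep1os, B3gat2, Cd247 and Pmch reach this overlap, whereas Acat3, Far2 and Samd11 overlap by less.

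A group of 169 genes rich in developmental regulators (22.5% against 0.968% of other genes, by a name pattern drawn up after the data were seen) was higher in D395A replicate 1 and KO replicate 2, against 16 genes with the reverse. RNA of neural cells stays open: 18 measured neuronal markers differed between the D395A libraries by a median log2 ratio of 0.0941 while the group itself differed by 2.80, but most of them have a baseline that would hide a small share, and of the 6 that do not (median 0.20) Nefm stood at 2.09 against 0.333 CPM, with Celf4 at 6.22 against 2.99 CPM among the others. A bias of GC content or low expression is argued against by 831 matched genes, with a median of 0.117. Opposite-strand reads are argued against for the KO libraries, by a bound written after the level was seen: KO replicate 2 held 0.197 of the opposite-strand level of replicate 1. For the D395A libraries they stay open, since replicate 1 held 1.38 times the level of replicate 2 and the group lay within an opposite-strand gene 1.65 times as often as other genes, between the bounds of the test.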

How the results depend on the processing

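Chosen after the data had been seen were the settings without genes that overlap on the opposite strand, without chromosomes 8, 11 and Y, without D395A replicate 1 and KO replicate 2 together, and the crossed block; the others were fixed before. Mettl3 stayed lower in KO and in D395A, past the test, in every setting that keeps the gene; the setting without genes that overlap on the opposite strand drops it. Over all settings the calls ranged from 8262 to 10801 for KO against WT, 8791 to 11420 for D395A against WT, 6442 to 8365 for D395A against KO, and 6054 to 7925 for shared changes, each within 1.5 times the reported count. The settings without opposite-strand genes and without chromosomes 8, 11 and Y are not new fits. Genes kept there have the fold changes of the main fit, and the lowest count of each range comes from dropping opposite-strand genes. The correlation between the fold changes of the mutant lines was 0.697 without a filter and 0.704 with the stricter filter. It was 0.644 to 0.792 leaving out 1 library, and the cause was not tested. Camera with an estimated correlation called 0, 0 and 0 lists, and fry called 23, 23 and 16, as fry compares a list with no other genes. Without a filter on low counts, camera at the preset correlation called 7, 14 and 12 lists, against 7, 10 and 13 in the main fit. Leaving out 1 library gave 6 to 8, 9 to 12 and 11 to 15 lists. With the stricter filter, which tests fewer genes, 2535, 2848 and 1626 genes changed at least 2-fold. With replicate number as a block, 10220, 10843 and 7832 genes were called, and 7146 for D395A against KO with the crossed block; the numbers do not pair the libraries, with correlations between same-numbered libraries of 0.0141, 0.00964 and -0.210. Of the named genes' values under other settings, 14481 stayed on their side of the threshold, 220 lost the call and 123 gained one. A reversed direction with a call in either setting was seen in 0. For single lists these were 980, 47, 53 and 0. Changes of direction with no call in either setting are counted among those that stayed, as for fibroblast markers in D395A against KO under fry. No scaling moved the median of all genes by over 0.1. Fits with 1 library left out assume that the lone library varies like the other groups. Depth limits genes near the floor, where ratios span wide intervals.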

Other observations

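The test of exon density was written before its result was seen; the gene families were chosen after the data had been seen.

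Genes of other cell types and states moved in both lines without a call for the list. Of 21 fibroblast markers, 10 rose and 4 fell in KO (adjusted p = 0.184; 12 and 4 adjusted over the list alone), and 12 rose and 7 fell in D395A (adjusted p = 0.348). Fstl1, a secreted glycoprotein, rose from 16.2 ± 0.25 CPM to 125 ± 4.66 CPM in KO, and fibrillin 1 (Fbn1) and collagen V (Col5a1) rose by 2.96 ± 0.12 and 2.12 ± 0.08, while vimentin (Vim) fell by 1.66 ± 0.07. Mesendoderm genes moved both ways, 5 higher and 4 lower of 16 in KO (adjusted p = 0.734) and 4 higher and 6 lower in D395A (adjusted p = 0.597, median -0.24, mean 0.01). Lefty1, an inhibitor of Nodal, rose by 3.52 ± 0.14 in KO, the repressor Snai1 by 3.74 ± 0.21, and Nodal itself by 1.05 ± 0.07. Trophoblast genes counted 7 higher of 15 in KO (adjusted p = 0.184) and 8 higher and 3 lower in D395A (adjusted p = 0.192). HOX genes counted 14 higher and 1 lower of 35 in KO (adjusted p = 0.139) and 22 higher and 7 lower in D395A (adjusted p = 0.245). Genes of the interferon and double-stranded RNA response counted 5 higher and 10 lower of 24 in KO (adjusted p = 0.536) and 9 and 10 in D395A (adjusted p = 0.789). Ifitm1 and Bst2 rose by 1.67 ± 0.06 and 1.74 ± 0.09 in KO, whereas Oas1a and Xaf1 changed by -1.61 ± 0.13 and -0.98 ± 0.07.

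Other lists passed in neither comparison with WT. DNA methylation genes counted 4 higher and 9 lower of 15 in KO (adjusted p = 0.396) and 4 and 8 in D395A (adjusted p = 0.325), and silencers of endogenous retroviruses 6 and 12 of 23 (adjusted p = 0.377) and 9 and 11 (adjusted p = 0.610). Mitochondrial ribosome genes counted 34 higher and 20 lower of 73 in KO (adjusted p = 0.420) and 30 and 25 in D395A (adjusted p = 0.789), and nuclear genes of oxidative phosphorylation 34 and 16 of 74 (adjusted p = 0.420) and 27 and 23 (adjusted p = 0.656). Small RNA genes counted 23 higher and 38 lower of 188 in KO (adjusted p = 0.445) and 22 and 29 in D395A (adjusted p = 0.409, where the test pointed down and the mean was 0.06). Adjusted over the list alone, the KO counts were 6 higher for trophoblast, 11 higher for HOX, 13 lower for retroviral silencers, and 13 higher and 27 lower for small RNA, and the D395A counts for small RNA were 20 and 10. The other counts of these lists stayed as given. Lists called in 1 comparison gave these adjusted p in the other: in KO, neuroectoderm 0.724, formative and primed 0.614, the 2-cell-like state 0.499, cholesterol 0.642, histones 0.642, ribosomal proteins 0.377, Wnt targets 0.396 and blood and endothelium 0.642. In D395A against WT they were 0.149 for extraembryonic endoderm, 0.0763 for integrated stress, 0.610 for blood and endothelium, and 0.822 for ERK feedback, whose median was 0.07 and mean -0.18. The direct test of D395A against KO called none of m6A machinery (0.911), circular RNA factors (0.718), p53 targets (0.603), germline (0.597), proteasome (0.182), extraembryonic endoderm (0.332), fibroblast (0.911), mesendoderm (0.271), trophoblast (0.603), interferon (0.664), HOX (0.706), DNA methylation (0.654), retroviral silencing (0.603), mitochondrial ribosome (0.277), oxidative phosphorylation (0.339) or small RNA (0.829).

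In some gene families most members were called in 1 direction. All 9 Xlr genes measured were lower in both KO and D395A. Of 7 Magea genes 4 were lower in KO and 7 in D395A, and of 11 Rhox genes 9 and 7 were lower. All 5 Zscan4 genes were higher in D395A than in WT. The direct test of D395A against KO called all 5 Zscan4 genes higher. Of 22 gamma protocadherins, 1 was higher and 5 lower in KO, and 15 were higher in D395A. Other families moved both ways. Collagen genes counted 16 higher and 5 lower of 33 in KO, and 17 and 7 in D395A, and keratin genes 3 and 4 of 12 in KO, and 4 and 4 in D395A.

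Genes with few exons per kb of transcript were higher in both mutant lines. Over 8007 protein-coding genes with a mean log2 CPM above 3 outside chromosomes 8, 11 and Y (a restriction set when the test was run), exons per kb and the log2 fold change correlated with Spearman rho = -0.204 for KO and -0.231 for D395A against WT, but -0.0640 for D395A against KO and 0.0258 between the WT libraries. Medians went from 0.23 in the group with the fewest exons per kb (median 1.04) to -0.12 in that with the most (6.48) in KO, and from 0.29 to -0.16 in D395A. Long internal and terminal exons carry more m6A, so this is consistent with such transcripts being more abundant without METTL3 activity. Both comparisons share the WT libraries, so a trait of these alone could give the same result, and m6A was not measured here. After adjusting for GC content, length and expression the values were -0.229, -0.255 and -0.0646, and -0.0530 between the WT libraries.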
